A study of Homo sapiens with 6 samples.

How the data were processed

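The series measured mRNA by RNA sequencing in 6 libraries of HBE cells, 3 transfected with cGAS siRNA and 3 with control siRNA. Groups and replicate numbers were taken from the sample titles. Per the labels, the cells came from a repository, were transfected in 6-well plates, and total RNA was extracted with TRIzol and made into libraries by a standard Illumina protocol. The sequences of the siRNAs and the time from transfection to harvest are not given in the sources used here.

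The authors deposited 1 table per library of expected counts per gene symbol, that is, estimated numbers of reads that need not be whole, not scaled for library size or gene length. That unit was read from the values: about 86.1% to 86.4% of the values in each library were whole, the rest had decimals, and the totals differed between libraries. Per the submitters' processing notes the genome build was GRCh38 and the tools were HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12. Their roles, the annotation and any read filter are not given in the sources used here. RSEM divides reads that fit several transcripts in proportion to an estimate, so near-identical genes can borrow counts from each other. Whether strand was used in counting is not given, so overlapping genes on opposite strands may share reads. The tables held none of the 13 mitochondrially encoded mRNAs, which were not analysed here.

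Expected counts were rounded to whole numbers, genes were kept by edgeR's filterByExpr (12972 of 17443), and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are cGAS siRNA minus control siRNA. Standard errors were obtained as the absolute log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled totals and are given as mean ± SD over 3 libraries. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members (32 of 38), with Benjamini-Hochberg adjustment over the lists. Of these, 12 were called, 10 up and 2 down. With an estimated correlation none was called at a threshold of 0.05, and the adjusted p of the 12 lay between 0.357 and 0.426. For 27 of the 32 lists the number of members past the test was equal when adjusted over the list alone, and for the others it differed by 1. CGAS was also tested by a two-sided exact permutation test of log2(CPM + 1) over the 20 ordered splits. Counting intervals are exact at 95% and, since reads carry no molecular identifiers, cover counting error only.

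The lists of genes, the tests and the rule for naming genes were fixed before the data were examined. Named are CGAS and every tested member of the cGAS-STING list; among genes past the threshold whose 3 libraries of one group all lie above those of the other, with at least 5 CPM in the higher group, the 10 largest increases and the 10 largest decreases; for each list described, up to 4 members with the smallest p past the threshold, or up to 2 with the smallest p where none passed; and the 5 genes with the smallest p. A few genes named beside control replicate 3 (TNFAIP3, IFI6 and ISG15 and those in the closing observations) were chosen after their values were seen.

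The procedure was tested on counts simulated from these libraries, with genes changed by known amounts. Of the changed genes tested, 30.6% were called at a log2 change of 0.2, 70% at 0.5, 90% at 1 and 100% at 2, and 9 of 154 calls were false, over 12884 genes. Only a small part of the genes was changed there, up and down alike, whereas 70.3% of tested genes were called in the data. The simulation therefore does not show the error rate, or how the scaling behaves, at such a share. The recovery required at a log2 change of 1 was lowered after it came out at exactly 90%. Gene positions were taken from GENCODE release 29, which is on GRCh38, the build of the processing notes. By symbol or an older symbol 17000 of 17443 genes were placed (97.5%).

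For the search of 3′ UTRs, the protein-coding transcript with the longest 3′ UTR was taken for each gene, and 12669 of 12972 tested genes (97.7%) had a 3′ UTR of at least 50 bases. A first run searched fewer genes; older gene symbols were then added to the match, and the values given are those after that change. The log2 fold change, limited to ± 2.0, was regressed on the presence of each heptamer found in at least 50 genes, with log length, GC content and mean expression and the square of each as covariates. The largest absolute statistic over 100 shufflings of the genes, 4.99, served as the limit. A heptamer planted with an effect of −0.25 in shuffled data ranked first and its effect was recovered as −0.234. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.

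Alternatives planned in advance were no filter, a filter of at least 50 counts in at least 3 libraries, DESeq2 size factors in place of TMM, DESeq2 1.42.0 as the test, a robust fit, the replicate number as a block, leaving out each library, a threshold of 0.01, camera with an estimated correlation, and fry. Others planned for normalized values only (other pseudocounts, median centring, quantile normalization and limma without a trend) were not run, since the files hold counts. For DESeq2 and the robust fit the lists were tested by applying the same camera test to signed z values of the p of each fit (cameraPR). Scaling by library totals alone, upper-quartile factors and a test against a minimum fold change were added after the data were examined.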

Results

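RNA was sequenced from HBE cells, a human bronchial epithelial cell line, after transfection with an siRNA against cGAS or with a control siRNA. cGAS, encoded by CGAS, is the enzyme that binds DNA in the cytosol and makes cGAMP, the messenger that activates STING. The 6 libraries formed 2 groups of 3, and the comparison asks how the transcriptome of these cells differs between cGAS siRNA and control siRNA. Total expected counts lay between 15274107 and 15736801 per library, so depth was nearly equal. The files listed 17443 gene symbols, of which 550 stood at 0 in every library and 12972 had enough counts to be tested. The labels number the samples of each group from 1 to 3 and do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

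The libraries separated by group. The first principal component of log2 CPM (counts scaled to library size) held 81.5% of the variance and parted the 3 cGAS siRNA libraries from the 3 control libraries. The second component held 7.24% and set control replicate 3 apart from control replicates 1 and 2. Replicates differed by little more than the sampling noise of counts: the chi-square per degree of freedom over genes lay between 1.52 and 1.63 within the cGAS siRNA group and was 1.47 between control replicates 1 and 2. It rose to 2.72 and 2.57 between control replicate 3 and control replicates 1 and 2, against 57.5 to 62.0 between libraries of different groups. The biological coefficient of variation was 2.73%.

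CGAS (chromosome 6, positions 73413515 to 73452276, GRCh38) was near the lower limit of measurement in every library. The expected counts were 16.2, 12 and 19 in cGAS siRNA replicates 1 to 3 and 17, 15.9 and 46 in control replicates 1 to 3. Mean expression was 1.01 ± 0.233 CPM (SD, n = 3) with cGAS siRNA and 1.71 ± 1.12 CPM (SD, n = 3) with control siRNA. The log2 fold change was −0.76 (SE 0.38), which did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0839). A two-sided exact permutation test of the 6 values gave p = 0.5, where 0.1 is the smallest p that 3 against 3 allows. The ratio of summed counts was 0.593, with a 95% counting interval of 0.402 to 0.857. Without control replicate 3 the ratio was 0.95 (0.592 to 1.52), the log2 fold change was −0.09 and the edgeR adjusted p was 0.823. Without control replicate 1 or control replicate 2 the log2 fold change was −0.99 or −1.02 and the call was made (edgeR adjusted p = 0.0309 and 0.0283). In counts simulated at the level of CGAS, a log2 change of −1 was called for 19% of genes and one of −2 for 98.0%. Few genes were changed there, whereas 70.3% of tested genes were called in the data. The adjusted threshold was therefore stricter in the simulation, and the 19% is not the power for CGAS in these data. Without control replicate 3 a reduction of CGAS mRNA was not detected, and the groups are named by their labels throughout.

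**Figure D1:**
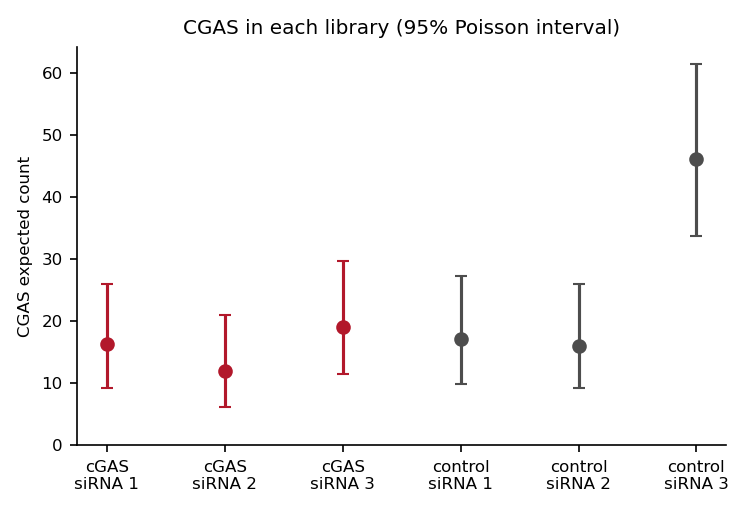
Expected count of CGAS (vertical axis, starting at 0) in each of the 6 libraries, with 95% Poisson intervals that cover counting error only; red, cGAS siRNA; grey, control siRNA. Of the points, 5 lie between 12 and 19 counts with overlapping intervals, and control replicate 3 lies at 46.

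Other members of the cGAS-STING pathway changed in both directions. Of 25 tested members, 10 rose, 9 fell and 6 did not pass the test, with 19 past it adjusted over the list alone. STING1, the receptor of cGAMP (chromosome 5, positions 139475534 to 139482935, GRCh38), fell from 82.4 ± 2.53 to 53.9 ± 3.10 CPM (SD, n = 3), a log2 change of −0.61 (SE 0.05, edgeR adjusted p = 1.9e-09). STIM1, a calcium sensor of the endoplasmic reticulum that binds STING, fell from 114 to 62.0 CPM (log2 −0.88), and SAMHD1, a dNTP-degrading enzyme, from 64.8 to 38.0 CPM (log2 −0.77). NLRC3 fell from 1.75 to 0.836 CPM. IFI16, DDX41, G3BP1, PQBP1 and TMEM203 fell by log2 changes of −0.12 to −0.40. ENPP1, which hydrolyses cGAMP outside cells, rose 2.90-fold from 1.32 to 3.84 CPM, and the kinase gene IKBKE rose 1.61-fold from 24.0 to 38.7 CPM. The 3 genes of RNase H2, RNASEH2A, RNASEH2B and RNASEH2C, rose 1.68-fold, 1.32-fold and 1.16-fold. TRIM56, NLRX1, ZCCHC3, BANF1 and ZDHHC1 rose by log2 changes of 0.13 to 0.42. The call of ZDHHC1 (edgeR adjusted p = 0.0453) was lost under 7 of the 14 alternatives, among them DESeq2 (adjusted p = 0.157). Besides CGAS, the members that did not pass were TBK1 (52.3 against 49.9 CPM), IRF3 (51.7 against 51.6), TREX1 (9.51 against 10.9), HMGB1 (318 against 332) and TRIM32 (52.9 against 49.6). As a set the list was not called by camera (adjusted p = 0.916).

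Across the transcriptome 9122 of 12972 tested genes (70.3%) differed between the groups, 4583 higher and 4539 lower with cGAS siRNA. Most of these differences were small: the median absolute log2 change of the changed genes was 0.41 and 60.3% of them changed by less than 0.5. A change of at least 2-fold was found for 1195 genes, 721 higher and 474 lower, and one of at least 4-fold for 106 and 63. In 72.7% of tested genes the 3 libraries of one group all lay on the same side of the 3 of the other, against 10% by chance. All counts come from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 9379 genes had an unadjusted p under 0.05. Against a minimum change of 1.5-fold, a test chosen after the data were examined, 1829 genes passed, 1061 higher and 768 lower.

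**Figure D2:**
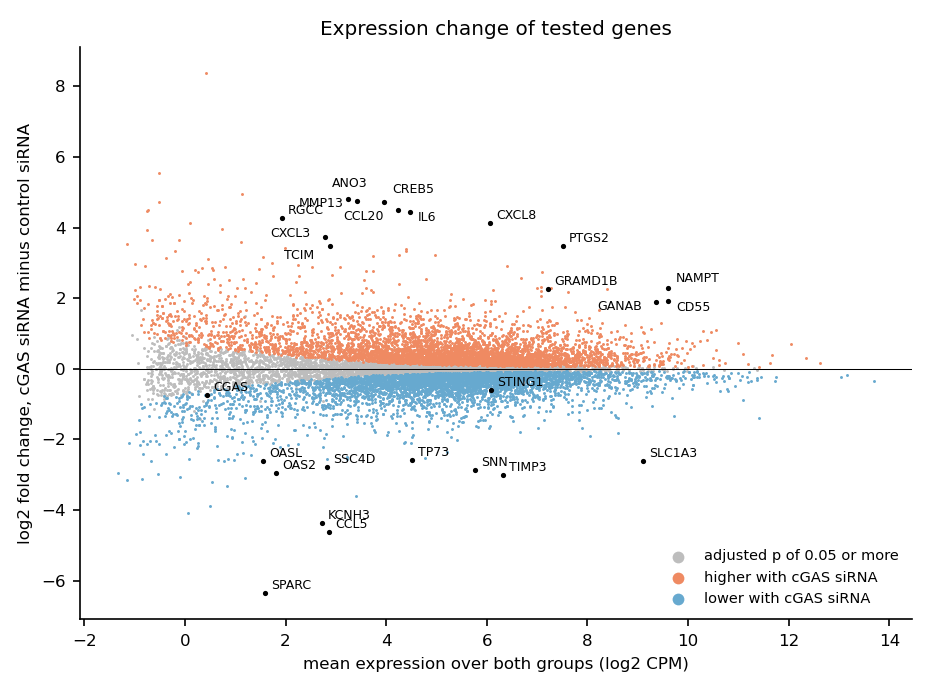
Log2 fold change, cGAS siRNA minus control siRNA (vertical axis), against mean expression in log2 CPM (horizontal axis) for 12972 tested genes; coloured points pass an edgeR adjusted p of 0.05, grey points do not. Labelled genes are the 10 largest increases and decreases among those with at least 5 CPM, the 5 smallest p, CGAS and STING1; IL6, CXCL8 and PTGS2 lie above 3 and TIMP3, SNN and SLC1A3 below −2.

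The 10 largest increases were taken among genes with separated libraries and at least 5 CPM in the higher group. IL6, the cytokine interleukin 6, rose from 1.95 ± 0.970 to 42.2 ± 1.63 CPM (21.6-fold), CCL20, a chemokine for CCR6-bearing lymphocytes and dendritic cells, from 1.58 ± 0.163 to 36.0 ± 4.35 CPM (22.7-fold) and CXCL3 from 0.952 to 12.8 CPM (13.3-fold). PTGS2, the inducible cyclooxygenase, rose from 30.2 ± 6.50 to 335 ± 9.57 CPM (11.1-fold; SD, n = 3 in each). CXCL8, encoding interleukin 8, stood at 126 ± 13.2 against 7.25 ± 7.46 CPM (17.4-fold), and TCIM at 13.5 against 1.22 ± 1.67 CPM (11.1-fold). In both, control replicate 3 stood above the other controls: without it the increase was 42.5-fold for CXCL8 and 50.6-fold for TCIM. TCIM stood at only 0.065 and 0.450 CPM in control replicates 1 and 2, so the size of its increase is uncertain. The calcium-activated scramblase family gene ANO3 rose 27.9-fold from 0.650 to 18.3 CPM and the collagenase gene MMP13 27.0-fold from 0.756 to 20.7 CPM. The transcription factor gene CREB5 rose 26.6-fold from 1.13 to 30.1 CPM and RGCC 19.3-fold from 0.368 to 7.25 CPM. Control levels this low lie near the lower limit of measurement, so the sizes of these increases are imprecise. The 10 genes had edgeR adjusted p-values of 3.2e-07 or below, and paralogous chemokines such as CXCL3 may share reads with close relatives.

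By the same rule, the 10 largest decreases included abundant transcripts. SLC1A3, a glutamate transporter (chromosome 5, positions 36606355 to 36688334), fell from 947 ± 42.6 to 154 ± 4.74 CPM, to 0.163 times the control level, with the smallest p of all tested genes (edgeR adjusted p = 1.9e-18). TIMP3, an inhibitor of matrix metalloproteinases (chromosome 22, positions 32801701 to 32863043), fell from 142 ± 4.51 to 17.4 ± 1.17 CPM, SNN to 13.0 CPM, 0.137 times the control level, TP73, a p53 family member, from 39.0 to 6.54 CPM, SSC4D from 12.4 to 1.80 CPM and the potassium channel gene KCNH3 from 12.5 to 0.598 CPM. KCNH3 stood at 0.0485 times the control level, a log2 change of −4.37 that became −4.99 without cGAS siRNA replicate 2. The other 4 of the 10 largest decreases rested largely on control replicate 3. CCL5 stood at 0.910, 3.60 and 37.2 CPM in control replicates 1 to 3 and at 0.452 to 0.647 CPM with cGAS siRNA, OAS2 at 1.95, 2.44 and 14.2 CPM against 0.774 to 0.828, and OASL at 1.89, 2.18 and 11.2 CPM against 0.582 to 1.02. SPARC had 3 counts in all over the cGAS siRNA libraries and 273 over the controls, a ratio of 0.0109 (95% counting interval 0.0022 to 0.0322). Without control replicate 3, whose SPARC level was 15.1 CPM, the SPARC ratio was 0.0474 (0.0094 to 0.148) and CCL5, OAS2 and OASL stood at 0.248, 0.361 and 0.400 times the control level. All 4 remained called without it and none passed in the robust edgeR fit (adjusted p = 0.121 for CCL5, 0.0956 for OAS2, 0.0983 for OASL and 0.0772 for SPARC).

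The other genes with the smallest p were abundant transcripts that rose. GANAB, the catalytic subunit of glucosidase II (chromosome 11, positions 62624826 to 62646726), rose from 276 ± 5.40 to 1031 ± 9.89 CPM. GRAMD1B, a sterol transfer protein gene, rose from 51.7 to 246 CPM. NAMPT, the rate-limiting enzyme of NAD salvage, rose from 264 to 1280 CPM, and CD55, a brake on complement, from 322 to 1221 CPM. These 4 genes had edgeR adjusted p-values of 8.5e-18 or below.

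Genes with either of the heptamers GCTGTCA and ACGTGAA in their 3′ UTRs were lower with cGAS siRNA across the transcriptome, a pattern found in a search of these data. Of the genes named in this text that fell, GCTGTCA occurred in STIM1, G3BP1, TIMP3, OAS2, SLC1A3, TP73, ZC3HAV1, IRF1, CDKN1A, H2BC21, SREBF2, ELOVL5, BMF, TP63, AJUBA, PTPN14, AGO2, HSPD1, HSP90AA1 and HSPA4L, and ACGTGAA in NEK7, CRIM1, DICER1 and AGO2. Of those that rose, GCTGTCA occurred in CREB5, PDIA3, IER3, PECAM1 and GRAMD1B, and ACGTGAA in PHLDA1.

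Inflammatory and early response genes rose together. Of 27 tested NF-kB cytokines and targets, 26 rose and 1, CCL5, fell, with a median log2 change of 1.36 (camera adjusted p = 9.4e-09, and adjusted p = 0.357 with an estimated correlation). IL1A, encoding interleukin 1 alpha, rose 4.63-fold to 223 CPM, and IER3, an early response gene, 4.50-fold to 322 CPM. In control replicate 3, 5 of the 22 members with enough counts stood at least 1.5-fold above the other controls, TNFAIP3 among them at 75.4 against 26.0 and 25.3 CPM. Without that library 26 rose and the median was 1.56. Among senescence-associated secreted factors, a list that shares IL6, CXCL8, IL1A and other cytokines with the first, 16 of 22 rose and 5 fell (camera adjusted p = 0.00438, and adjusted p = 0.426 with an estimated correlation). The growth factor genes AREG and VEGFA rose 10.2-fold to 38.4 CPM and 2.31-fold to 376 CPM, and 4 of 20 counted members stood at least 1.5-fold above the other controls in control replicate 3. Of 26 immediate early and MAPK feedback genes, 18 rose and 2 fell, with 21 past the test adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.358 with an estimated correlation). The phosphatase genes DUSP1 and DUSP4, which dampen MAPK signalling, rose 4.18-fold to 216 CPM and 3.34-fold to 288 CPM, and PHLDA1 rose 5.90-fold to 175 CPM. The inflammasome list was split, 2 up and 6 down of 11 tested, and was not called (camera adjusted p = 0.362): IL1B and CASP4 rose 1.86-fold and 1.39-fold, while NEK7 and GSDME fell to 0.614 and 0.773 times the control level.

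Interferon-stimulated genes moved the other way. Of 45 tested members of the type I interferon response list, 33 fell, 3 rose and 9 did not pass, with 36 past the test adjusted over the list alone and a median log2 change of −0.40 (camera adjusted p = 2.6e-05, and adjusted p = 0.426 with an estimated correlation). STAT2, a transcription factor of interferon signalling, fell from 113 ± 1.85 to 52.6 ± 0.656 CPM, and the antiviral factor gene SAMD9 from 201 to 126 CPM. The membrane protein genes IFITM3 and IFITM1, members of a family whose related genes may share reads, fell from 1931 to 1255 CPM and from 349 to 226 CPM. Control replicate 3 held higher levels of 7 of the 41 members with enough counts, at least 1.5-fold above the other controls, among them IFI6 with 9.08 against 1.95 and 1.61 CPM and ISG15 with 16.8 against 4.94 and 5.27 CPM. Without that library 32 members fell, 4 rose and the median was −0.40 (camera adjusted p = 9.8e-05). Of 16 RNA sensing genes, 10 fell and 2 rose, without a call as a set (camera adjusted p = 0.0723). TRIM25, ZC3HAV1, IRF1 and the helicase gene DDX3X fell to between 0.713 and 0.847 times the control level. MHC class I presentation genes were split, 10 up and 9 down of 20 (camera adjusted p = 0.852). HLA-E, which shares sequence with other class I genes, fell to 0.685 times the control level, while the chaperone genes CALR and PDIA3 rose 2.10-fold and 1.33-fold.

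**Figure D3:**
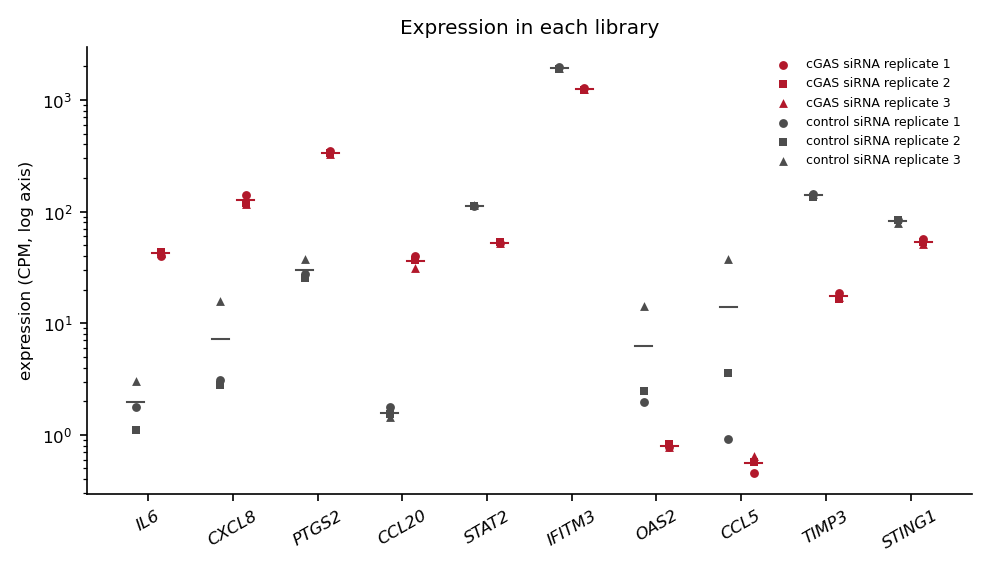
Expression in CPM (vertical log axis) of 10 genes in each library; red, cGAS siRNA; grey, control siRNA; marker shapes are replicates and short lines are group means. CCL20, STAT2, IFITM3, TIMP3 and STING1 are tight within groups, whereas control replicate 3 lies above the other controls for IL6, CXCL8, PTGS2, OAS2 and CCL5, the last at 37.2 CPM.

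Proliferation genes rose throughout. All 35 tested G2/M and mitosis genes rose, 28 of them at least 2-fold, with a median log2 change of 1.22 (camera adjusted p = 5.7e-13, and adjusted p = 0.358 with an estimated correlation). TOP2A, the DNA topoisomerase of dividing cells, rose from 161 ± 7.50 to 337 ± 6.52 CPM. ANLN, a scaffold of the cleavage furrow, rose 2.35-fold to 221 CPM, the kinetochore gene CENPF 2.61-fold to 219 CPM and the mitotic transcription factor gene FOXM1 2.32-fold to 163 CPM. All 35 G1/S and DNA replication genes rose as well, with a median of 0.92 (camera adjusted p = 2.2e-11, and adjusted p = 0.357 with an estimated correlation). RRM1 and RRM2, the subunits of ribonucleotide reductase, rose 2.21-fold to 329 CPM and 3.57-fold to 107 CPM, the transcription factor gene E2F1 4.10-fold to 34.9 CPM and the helicase subunit gene MCM6 1.89-fold to 103 CPM. Of 33 DNA repair genes, 26 rose and 1 fell (camera adjusted p = 5.1e-07, and adjusted p = 0.358 with an estimated correlation), with EXO1, BRCA1, FANCD2 and LIG1 rising 2.07-fold to 3.16-fold. Only 6 of the replication-dependent histone genes were tested and the list was not called (camera adjusted p = 0.632). H2BC5 and H2BC12 rose 2.67-fold and 1.39-fold and H2BC21 fell to 0.765 times the control level, in a family whose near-identical members may share reads. The p53 targets were not called (12 down and 6 up of 25, 19 past the test adjusted over the list alone, camera adjusted p = 0.218). Among them CDKN1A, the cell cycle inhibitor p21, fell from 340 to 255 CPM, SESN1 from 66.8 to 23.6 CPM, PHLDA3 from 124 to 82.6 CPM and TP53INP1 from 34.5 to 17.1 CPM.

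Stress response programmes of the endoplasmic reticulum, amino acid supply and redox balance rose. Of 22 unfolded protein response genes, 17 rose and 3 fell (camera adjusted p = 1.3e-04, and adjusted p = 0.357 with an estimated correlation). HSPA5, the chaperone BiP, rose from 911 ± 4.08 to 1890 ± 12.9 CPM, HSP90B1 from 961 to 1706 CPM, XBP1 from 107 to 326 CPM and ATF4 from 182 to 447 CPM. Of 25 ATF4 targets of the amino acid response, 17 rose and 4 fell (camera adjusted p = 1.9e-04, and adjusted p = 0.358 with an estimated correlation). SLC7A11, the cystine importer, rose 7.45-fold to 148 CPM, PHGDH, the first enzyme of serine synthesis, 2.42-fold to 132 CPM, and the tRNA synthetase genes AARS1 and GARS1 2.57-fold and 2.40-fold. Of 26 NRF2 targets, 21 rose and 2 fell (camera adjusted p = 1.7e-05, and adjusted p = 0.357 with an estimated correlation). The aldo-keto reductase genes AKR1C1 and AKR1C2 rose 4.88-fold and 4.86-fold, although their sequences are so alike that reads may be split between them, and ME1 rose 2.84-fold to 112 CPM. The heat shock list was not called (10 down and 5 up of 16, camera adjusted p = 0.296): HSP90AA1, HSPD1 and HSPA4L fell to 0.640, 0.655 and 0.695 times the control level and DNAJB4 rose 1.77-fold. Neither the autophagy and lysosome list (13 down and 9 up of 28, camera adjusted p = 0.501) nor the AHR list (3 up and 2 down of 8, camera adjusted p = 0.632) was called. In the first CTSL rose 2.62-fold to 320 CPM and LAMP1 fell to 0.763 times the control level. In the second the receptor gene AHR rose 2.46-fold and ALDH1A3 fell to 0.472 times the control level.

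**Figure D4:**
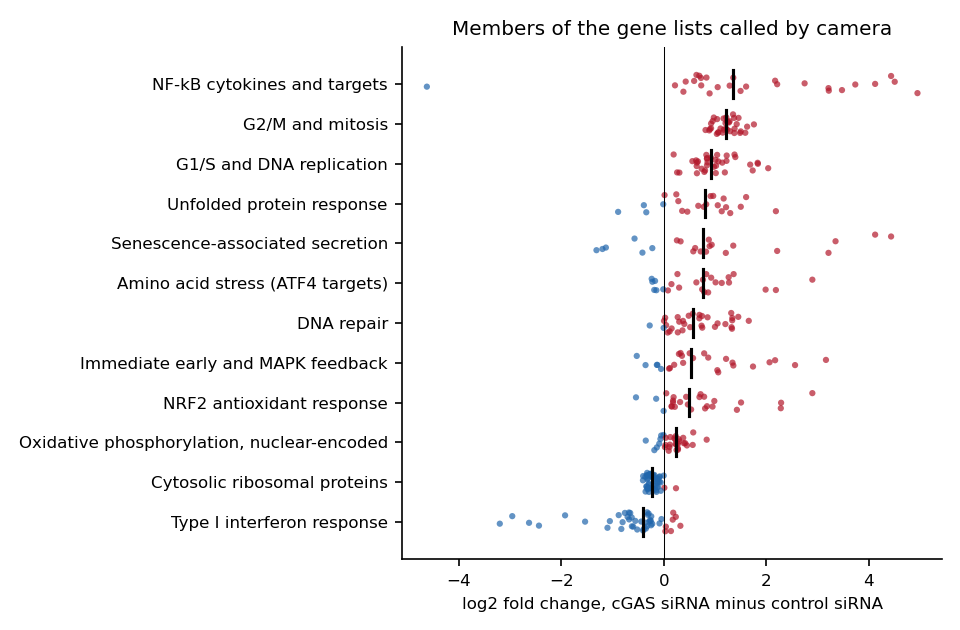
Log2 fold change, cGAS siRNA minus control siRNA (horizontal axis), of each tested member of the 12 gene lists called by camera with the preset correlation; points are genes, red above 0 and blue below, and black bars are list medians. The medians run from −0.40 for the type I interferon response to 1.36 for NF-kB cytokines and targets.

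Of 32 nuclear-encoded genes of oxidative phosphorylation, 22 rose and 4 fell with a median log2 change of 0.23 (camera adjusted p = 0.00438, and adjusted p = 0.357 with an estimated correlation). NDUFV1, ATP5PB and ATP5MC1 rose 1.31-fold to 1.48-fold. Of 50 cytosolic ribosomal protein genes, 44 fell and 1 rose, with 46 past the test adjusted over the list alone and a median of −0.22 (camera adjusted p = 6.4e-07, and adjusted p = 0.357 with an estimated correlation). RPLP0 fell from 2942 ± 32.6 to 2351 ± 4.06 CPM, RPS4X from 1880 to 1471 CPM and RPS3A from 1510 to 1140 CPM, in a family with many processed pseudogenes. Cholesterol synthesis genes were not called as a set (15 up and 5 down of 24, camera adjusted p = 0.191). SREBF2, the transcription factor that drives the pathway, fell from 277 ± 3.94 to 113 ± 1.95 CPM. Its known targets INSIG1 and FDPS rose 2.23-fold and 2.12-fold. Among fatty acid synthesis genes (8 up and 3 down of 14, camera adjusted p = 0.0537), ACSL4 and ACACA rose 2.10-fold and 1.56-fold, while ELOVL5 fell to 0.429 times the control level. The glycolysis and hypoxia list was split, 17 down and 11 up of 28 (camera adjusted p = 0.501), with HK2 up 1.60-fold and EGLN3 and ALDOC at 0.546 and 0.694 times the control level.

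Epithelial identity genes moved in both directions. Of 23 tested basal and squamous epithelium genes, 10 rose and 10 fell (camera adjusted p = 0.760), and 3 of 19 counted members stood at least 1.5-fold above the other controls in control replicate 3. KRT5, the keratin of basal cells, fell from 545 ± 52.2 to 210 ± 13.3 CPM, TP63, the basal cell transcription factor, from 120 to 82.7 CPM and DST from 568 to 381 CPM, while LY6D rose from 180 to 307 CPM. Of 24 epithelial junction genes, 8 rose and 11 fell, with 20 past the test adjusted over the list alone (camera adjusted p = 0.294). CTNNB1, beta-catenin, rose from 731 to 1272 CPM and ST14 from 282 to 523 CPM, while DSP, desmoplakin, fell from 2092 to 1419 CPM and CTNND1 from 2138 to 1394 CPM. Of 23 mesenchymal and matrix genes, 10 rose and 7 fell (camera adjusted p = 0.631). The members with the smallest p were the basement membrane collagen genes COL4A1 and COL4A2 and CCN1, which rose 2.84-fold, 1.76-fold and 2.06-fold, and TGFBI, which fell to 0.680 times the control level. In control replicate 3, 3 of the 22 counted members of that list, SPARC among them, stood at least 1.5-fold above the other controls. Apoptosis genes were split, 11 up and 9 down of 24 (camera adjusted p = 0.900): CYCS rose 1.63-fold, while BMF and TNFSF10, which encodes TRAIL, fell to 0.195 and 0.247 times the control level.

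Markers of other cell types are given as levels, with cGAS siRNA before control siRNA. Of 5 tested secretory airway genes, 3 rose and 2 fell, and the list was not called (camera adjusted p = 0.632). MUC5AC, a gel-forming mucin that rose, stood at 38.6 ± 1.45 CPM with cGAS siRNA and 19.0 ± 1.24 CPM with control siRNA (SD, n = 3), SPDEF at 10.7 and 5.02 CPM, and BPIFB1 at 7.67 and 33.1 CPM. Ciliated cell genes were low: of 6 tested, 2 fell (FOXJ1 at 0.192 and 1.69 CPM, CAPS at 1.54 and 3.61 CPM) and 2 rose (TPPP3 at 1.35 and 0.433 CPM, RSPH1 at 1.69 and 0.735 CPM), and the list was not called (camera adjusted p = 0.916). The alveolar gene LAMP3 stood at 3.49 and 5.90 CPM, the fibroblast gene FAP at 8.40 and 6.44 CPM, and the macrophage genes CD68 and CD14 at 57.9 and 36.4 CPM and at 4.98 and 10.3 CPM. The endothelial genes CDH5 and PECAM1 stood at 21.4 CPM (0.403 times the control level) and at 19.9 and 6.55 CPM, and the lymphocyte gene GNLY at 1.47 times its control level of 8.22 CPM. IL7R stood at 7.67 and 2.84 ± 2.97 CPM, and its 2.70-fold increase became 6.71-fold without control replicate 3 and lost its call in DESeq2 (adjusted p = 0.113) and the robust edgeR fit (adjusted p = 0.138). No list of alveolar, fibroblast, macrophage, lymphocyte or endothelial genes had 5 tested members, so these were not tested as sets.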

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

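Scaling by library totals without TMM, upper-quartile factors and the test against a minimum change of 1.5-fold were chosen after the data were examined; the other alternatives were planned. The number of genes called at an adjusted p under 0.05 ran from 7984 with DESeq2 to 9231 without a filter on low counts, and every gene called both there and in the reported edgeR test kept its direction in all 14 alternative fits. With 1 library left out it lay between 8606 and 9037. The number changed at least 2-fold, 1195 in the reported test, ran from 843 with the stricter filter to 1493 without a filter, which test fewer and more genes of low count, and was 1161 with DESeq2 and 1225 to 1279 with 1 library left out. At a threshold of 0.01 there were 3992 genes up and 3919 down. Against a minimum change of 1.5-fold 1829 genes passed, fewer because that test asks for a larger change.

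The 12 called lists were called in all 14 alternative fits. With an estimated correlation camera called 0 lists, and fry, which tests each list without reference to other genes, called 29. With 1 library left out 12 to 13 lists were called. The camera calls therefore depend on the preset correlation.

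For CGAS the log2 fold change was −0.72 with the replicate block, where it passed the threshold (edgeR adjusted p = 0.0454), and ran from −1.02 without control replicate 2 to −0.09 (−0.0885) without control replicate 3. Adjusted p-values ran from 0.0283 to 0.823 over the alternatives. With at least 50 counts required in at least 3 libraries CGAS was not tested. The replicate numbers were checked for pairing: same-number residuals correlated at −0.0143, 0.0345 and −0.0769, so the block was used only here.

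The results that changed direction had not passed the threshold in the reported test, and the cause was not tested. IRF3 (log2) was −0.0099 without a filter, −0.0012 with DESeq2 size factors, −0.0012 with DESeq2, −0.0075 without TMM and −0.0012 with upper-quartile factors, and ran from −0.0178 to 0.0144 with 1 library left out. The adjusted p of lists that changed direction without being called was 0.939 (secretory) and 0.938 (ciliated) without a filter, 0.925 (apoptosis) with the stricter filter, 0.734 (cGAS-STING) and 0.636 (apoptosis) with DESeq2, 0.934 (cGAS-STING) and 0.994 (apoptosis) with the robust fit, and 0.989 (cGAS-STING and ciliated) with the replicate block. With 1 library left out it ran from 0.875 to 0.974 for cGAS-STING and from 0.826 to 0.975 for ciliated genes. By fry the apoptosis list was called downward (adjusted p = 0.000317). Over all named genes and alternatives, 2369 results kept direction and side of the threshold, 18 lost the call, 4 gained it and 8 changed direction; for lists these were 457, 12, 27 and 14.

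The alternatives chosen in advance for normalized values only (pseudocounts, median centring, quantile normalization, limma without a trend) were not run on counts. Depth limits genes at the level of CGAS, where a simulated log2 change of −1 was called for 19% of genes. Few genes were changed in that simulation, so its adjusted threshold was stricter than in the data and the share is not the power for CGAS.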

Other observations

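The RNA interference machinery list was not called (2 up and 8 down of 13, camera adjusted p = 0.0732). DICER1, which cuts precursor microRNAs, fell from 135 to 71.4 CPM, TNRC6A from 101 to 73.5 CPM and AGO2 from 84.8 to 67.4 CPM, while DROSHA rose from 88.1 to 153 CPM. Of 21 tested YAP/TEAD targets, 12 fell and 4 rose, with 17 past the test adjusted over the list alone (camera adjusted p = 0.0732). AMOTL2 fell from 214 to 93.0 CPM, AJUBA from 214 to 102 CPM, CRIM1 from 131 to 50.8 CPM and PTPN14 from 102 to 54.6 CPM. Of these 8 genes, DICER1, AGO2, AJUBA, CRIM1 and PTPN14 held at least 1 of the heptamers below in their 3′ UTRs.

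All tests on control replicate 3, CGAS and short sequences below were chosen after the pattern each concerns was seen, and of these the bounds for lowered genes in control replicate 3 and the octamer comparison were set before their values were computed.

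Control replicate 3 held transcripts that the other controls had at lower levels: of 11372 genes with at least 50 counts on average, 78 lay at least 1.5-fold above control replicates 1 and 2 and 16 at least 1.5-fold below. Reads or RNA from the cGAS siRNA libraries were argued against by 26 genes with at least 8 counts there and at most 2 over the other 5 libraries, such as SPRR2A (61 against 1) and HORMAD1 (15 against 0), examples chosen after their values were seen. A mislabelled cGAS siRNA library was argued against by correlations of at least 0.991 with the other controls, above the highest with a cGAS siRNA library (0.961). A share of RNA from another cell source may explain the pattern. In control replicate 3, 0.205 genes lay below per gene above (95% interval 0.112 to 0.354), between the bounds of 0.1 and 0.33 set in advance. By the same count the cGAS siRNA libraries, each against the others of its group, had 19 to 26 genes below and 12 to 18 above. The 16 genes below in control replicate 3 thus did not exceed the spread between replicates, and the ratio cannot decide. Another cell source therefore stays open beside a response of the cells in that sample. Which cells these would be was not tested.

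CGAS counts did not separate the groups. The extra transcripts of control replicate 3 are a candidate explanation for the lower ratio over all controls, since without that library the ratio was 0.950 (95% counting interval 0.592 to 1.52). A reduction of 4-fold or more hidden by low depth was argued against, since the interval over all controls began at 0.402. Whether CGAS mRNA was reduced earlier after transfection, or the protein was, is open: neither was measured here.

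Genes whose 3′ UTRs held either of 2 heptamers, GCTGTCA (1658 genes, effect −0.18) or ACGTGAA (482 genes, effect −0.28), were lower with cGAS siRNA. They made up 22.9% of genes that fell, 11.6% of those that rose and 12.6% of those that did not pass, shares not adjusted for UTR length. UTR length, GC content and expression were argued against by a statistic of −10.9 with these as covariates, beyond the shuffled limit of 4.99 (AGGAGAA, absent from CGAS mRNA, passed it upward with 6.09 in 3266 genes, effect 0.08, so passing it does not by itself point to siRNA matches), and a bias of whole transcripts by coding-sequence effects of at most 0.265 times those in 3′ UTRs for these 2, although CACGTGA, which overlaps the second, had effects of −0.13 in coding sequences and −0.19 in 3′ UTRs, so such a bias stays open for it. Matches to the 5′ end of siRNAs made against CGAS are a candidate explanation: the 2 octamers ranked first, CACGTGAA and TGCTGTCA, both occur in the CGAS coding sequence. Of the octamers searched 5.93% occur in CGAS mRNA, but the heptamers within these 2 had already been seen there, so that share is not their chance. Some high-ranked octamers with the same heptamers are absent from CGAS mRNA, such as ACGTGAAA and AACGTGAA (both −0.29, against −0.38 for CACGTGAA). Another is AGCTGTCA (−0.16, against −0.17 for TGCTGTCA), while GCTGTCAA (−0.21) and ACGTGAAG (−0.25) occur in that mRNA. Genes with the octamer fell more than those with only its heptamer for CACGTGAA (one-sided permutation p = 0.006) and not detectably for TGCTGTCA (p = 0.17), and the rule that 1 of the 2 sufficed was set after these values were seen. The siRNA sequences were not compared, STING1 and most changed genes held neither heptamer, and carriers such as GRAMD1B and IER3 rose, so this may concern a part of the changes only.

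Over the 10 splits of the 6 libraries into groups of 3, the real split called 9122 genes, 1195 at least 2-fold, and 12 lists, and the highest other split 0 genes, 0 at least 2-fold and 11 lists, so for each count 1 of the 10 splits reached the real value. With 10 splits no share under 0.1 can be had. Every other split placed libraries of both groups on each side, so the group difference widened the spread it was tested against. Its gene counts were therefore bound to be low and cannot decide on chance. For lists the other splits called 8 to 11. Each of them still carried part of the group difference, and camera compares genes with each other. The list counts therefore cannot decide on chance either.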
